A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

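Gene expression of 2 Saccharomyces cerevisiae strains was measured after galactose was added, on 24 Affymetrix YG_S98 arrays with 1 colour. The labels describe 8 conditions with 3 biological replicates each, total RNA, and labelling by in vitro transcription. They give times of 0, 20, 30, 40 and 60 with no unit, and minutes are assumed. The deposited table holds 1 intensity per probe set on a linear scale for 9335 probe sets, and the 2% trimmed mean is near 100.1 on every array, so each array had been scaled to a common level. The summary algorithm and its software are not given in the sources used here. Per the file headers, the instrument files give chip lot and hybridization settings, from which 4 hybridization rounds were read, and these files were used for technical grouping only.

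Values were transformed as log2 of the intensity plus a pseudocount of 1.4, the 10th percentile of the table. The array medians then ran from 4.72 to 5.15 and differed by more than 0.1, so the arrays were quantile normalized. Before that step the 60 control probe sets were left out. Of the others 6504 named 1 gene, 328 named several and 2443 named none, and those naming 1 gene were tested, with the brightest probe set for each gene, which left 5656 genes. Gene names came from the platform annotation and were matched by gene ID to a table of current yeast genes, which changed 0 names. Genome coordinates were not used. Strain markers were read gene by gene.

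Analysis used R 4.3.3 and limma 3.58.1. The 8 group means were fitted over all 24 arrays, without a replicate block, and 11 contrasts were tested with moderated t tests: 3 strain differences (before galactose, at 30 and at 60 min), 6 changes from time 0 (YSS37 at 30 and 60 min, YSS89 at 20, 30, 40 and 60 min) and 2 differences of responses (at 30 and 60 min). A gene was called at an adjusted p under 0.05 by limma with the Benjamini-Hochberg (BH) method over all genes of the contrast, and rises and falls in the report are called genes. The median standard error was 0.171 for strain differences and changes from time 0 and 0.242 for differences of responses. Within groups the arrays correlated over genes at r of 0.968 to 0.991, and genes are not independent replicates. The ACT1 ratio of 3' to 5' probe sets was 1.20 to 1.58. The same ratio was wider for 2 other control genes, 1.23 to 3.73 for YER148W and 1.7 to 4.72 for YER022W. Replicate c of YSS89 at time 0 had the lowest YER148W ratio, and replicate a of YSS89 at 20 min had the highest of both.

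The fixed lists were written from general knowledge of yeast: cytosolic RP genes (138 listed, 81 measured), RP genes with Abf1 promoter sites (7, 5), mitochondrial RP genes (70, 70), ribosome biogenesis (147, 146), RNA polymerase I and III (28, 28), translation factors (47, 39), galactose utilisation (9, 9), RP gene regulators (10, 10), Hsf1 chaperones (27, 27), general stress (39, 39), respiration and TCA cycle (49, 49), non-fermentable carbon use (32, 32), glycolysis and fermentation (22, 21), hexose transport (23, 17), amino acid biosynthesis (73, 71), histones (10, 4), cell cycle (42, 41), proteasome (33, 33), a-cell genes (7, 7) and alpha-cell genes (8, 4). Many RP and histone genes were not measured because their probe sets name more than 1 paralog. Lists were tested with camera of limma at a preset correlation of 0.01, with BH over all 220 tests of 20 lists in 11 contrasts, again with the correlation estimated from the data, and with fry. Members were also counted with BH over the list alone. The RP level of an array was the mean of its RP genes minus the median of all genes, compared by exact permutation of 3 against 3 arrays. The RP genes with Abf1 sites were compared with the other RP genes by 100000 permutations of gene labels.

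Genes named in the report came from a fixed rule: in 5 contrasts the 10 largest rises and the 10 largest falls among called genes whose 3 arrays all lay beyond the other 3, the regulators of RP genes, markers and GAL genes in every contrast, and for each list up to 4 members with the highest and lowest called values. From this choice some genes are not named, among them list members whose direction turned under an alternative. The rule, the contrasts, the lists and most other settings to be tried were fixed before the data were examined. Which of the rule's genes to leave unnamed was decided after the results were seen.

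Other settings fixed in advance were a replicate block by letter or by strain and letter, only the groups of a contrast in the fit, values as deposited, median centring, a pseudocount of 1 or of 6.2 (the 25th percentile), the dimmest 25% of genes left out, all probe sets one by one, the mean of the probe sets of a gene, a trended and robust prior, array weights, the round as a block, each array left out, the estimated correlation, fry, and direct strain differences. Settings chosen after seeing the data were the fit without replicates b and c of YSS89 at time 0, probe sets naming several RP genes added to the RP list, and contrasts within hybridization rounds. The method was tested on simulated data, drawn as normal noise around the mean and with the fitted spread of each gene, with 200 changed genes in each of 10 runs. For the strain difference before galactose 32.7%, 86.4% and 99.4% of changes of 0.5, 1 and 2 on the log2 scale were recovered, with 5.07% false calls, and for the difference of responses at 60 min 7.31%, 58.1% and 94.4%, with 3.28% false calls. A list shift of 0.4 was recovered as 0.41. The simulated noise was independent between genes and held no effect of the hybridization round, so these rates do not cover errors from either source. The simulated values were drawn on the normalized scale and not normalized again. Errors from the quantile step are thus not covered either. Raw image data were not used here.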

Results

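Messenger RNA levels of Saccharomyces cerevisiae were read on 24 Affymetrix YG_S98 arrays, with 5656 genes measured. Cells in log phase in YPLG medium received galactose to 2%. The control strain YSS37 has a tagged IFH1 under its own promoter and YSS89 has the same gene under the GAL1 upstream activating sequence. IFH1 encodes a coactivator that binds ribosomal protein (RP) gene promoters together with Fhl1. YSS37 was sampled at 0, 30 and 60 min and YSS89 at 0, 20, 30, 40 and 60 min, with 3 biological replicates in each of the 8 groups. The labels name no time unit, and minutes are assumed here. The arrays were hybridized in 4 rounds. The first held all YSS37 arrays but 1, the second held 1 YSS37 array at 60 min and the first YSS89 arrays, the third held later YSS89 arrays, and the fourth held replicates b and c of YSS89 at time 0 alone. On those 2 arrays the 25S rRNA control probe sets read 313 and 90.9, against 560 to 1056 on the other 22. All YSS37 arrays came from 1 chip lot, and no YSS89 array was recorded with that lot. For replicates b and c of YSS89 at time 0 no lot was recorded. Effects of lot and strain are thus not separated in direct comparisons of the strains. Changes are given as log2 values throughout.

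IFH1 was strongly induced by galactose in YSS89. Its signal was 26.4 ± 7.1 (SD, n = 3) at time 0, 1365 ± 66.1 at 20 min, 1296 ± 77.8 at 30 min, 1006 ± 29.2 at 40 min and 572 ± 13.7 at 60 min, a rise of 5.77 (54.5-fold, adjusted p = 4.14e-16) at 20 min and of 4.62 (24.6-fold, adjusted p = 2.11e-14) at 60 min. In YSS37 it moved from 20.8 ± 7.07 to 33.7 ± 4.23 at 30 min and 38.2 ± 4.37 at 60 min, a rise of 0.73 (adjusted p = 0.00149) at 60 min. The response of IFH1 was larger in YSS89 by 3.89 (adjusted p = 2.53e-09) at 60 min. Before galactose IFH1 was not called different between the strains (0.009, adjusted p = 0.974). HIS3, the marker placed in YSS89, was higher there before galactose (1.37, adjusted p = 0.00163), with signals of 16.9 ± 1.27 against 4.87 ± 2.18, the latter so low that the size depends on the pseudocount (0.92 with one of 6.2). TRP1, the marker beside the tag in both strains, was also higher in YSS89 at time 0 (0.62, adjusted p = 0.00189), and fell in YSS89 by 60 min (-0.71, adjusted p = 0.000296).

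The galactose genes rose in both strains. In YSS37 at 60 min the galactokinase gene GAL1 rose by 7.79, the permease gene GAL2 by 7.94, the transferase gene GAL7 by 8.0 and the epimerase gene GAL10 by 8.30. In YSS89 these rises were 7.80, 8.37, 8.21 and 8.84 at 20 min and 7.18, 7.37, 7.83 and 8.68 at 60 min. Signals of these 4 genes at time 0 in YSS37 were 3.53 to 10.6, near the pseudocount, so the sizes depend on it and understate the change. The regulators GAL3 and GAL80 rose by 2.86 and 1.99 in YSS37 at 60 min and by 1.65 and 2.15 in YSS89. GAL3 was the 1 member of the 9 galactose utilisation genes whose response at 60 min was called different between the strains (-1.21, adjusted p = 0.00031), and it was already higher in YSS89 before galactose (0.47, adjusted p = 0.0118). Compared directly at 60 min 4 of the 9 were lower in YSS89, GAL3 (-0.74), GAL2 (-0.73) and GAL1 (-0.48) among them. The response of GAL1 was not called different (-0.61, adjusted p = 0.0975). In YSS37 at 60 min 7 of the 9 rose and 2 fell, GAL4 (-0.86) and the phosphoglucomutase gene PGM2 (-1.22).

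**Figure D1:**
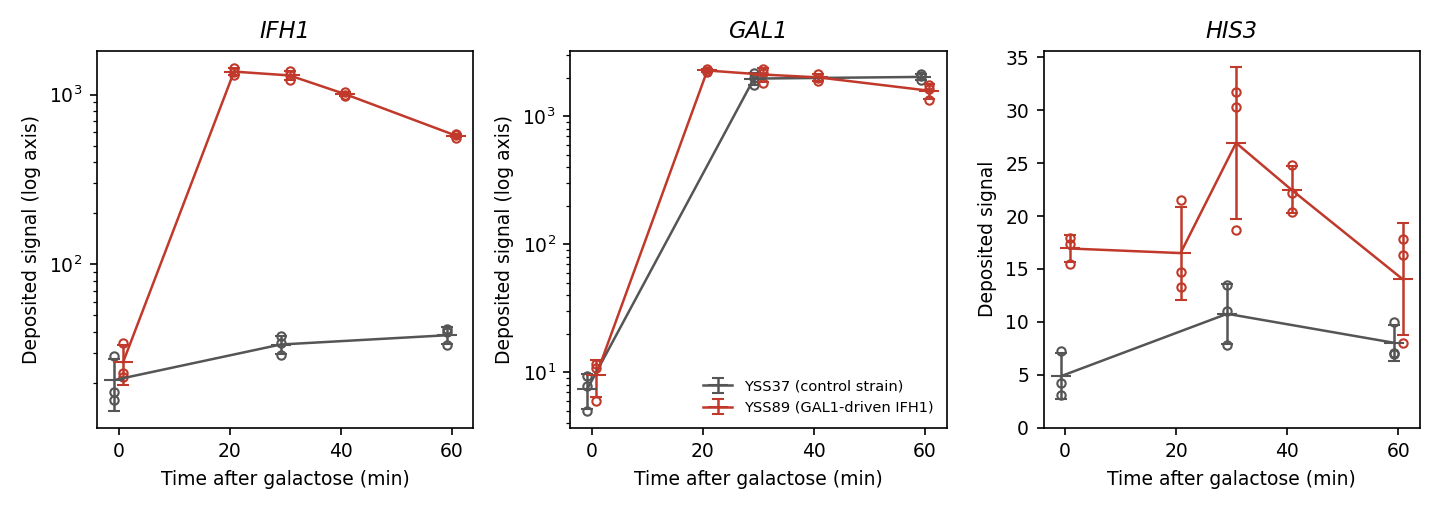
Deposited signal of IFH1, GAL1 and HIS3 in YSS37 and YSS89 by time after galactose. Circles are single arrays, and bars give the mean and SD of 3 arrays.

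In the control strain genes for non-fermentable carbon use fell after galactose and ribosome biogenesis genes rose. No culture without galactose was sampled over these times, so the effects of galactose and of time are not separated. At 60 min 1195 genes were higher and 1159 lower, and 365 and 353 of them changed at least 2-fold. In brackets the list medians here are followed by the adjusted p with an estimated correlation between genes. Of 146 ribosome biogenesis genes 142 rose and none fell, (1.31, 0.0309), as did 21 of 28 genes for RNA polymerase I and III (0.99, 0.0288) and 28 of 39 translation factor genes (0.51, 0.135). Among them were the RNA helicase gene DBP2 (2.78), REX4 (2.45), the polymerase I subunit genes RPA12 (2.15) and RPA43 (1.65), and the initiation factor genes TIF3 (0.94) and GCD1 (0.96). The uracil permease gene FUR4 (3.31), the adenine deaminase gene AAH1 (2.53), the cyclin-dependent kinase inhibitor gene FAR1 (2.56) and the open reading frame YKL068W-A (2.52) also rose. Of 41 cell cycle genes 20 rose and none fell (list adjusted p = 0.0937), among them the cyclin genes PCL1 (1.64) and CLB6 (1.60). Of 32 genes for non-fermentable carbon use 30 fell and none rose (-2.20, 0.0113), with the gluconeogenic FBP1 at -5.11 and the malate synthase gene MLS1 at -3.71. FDH1 (formate dehydrogenase, -4.17), YNL194C (-4.77), PRR2 (-4.48), RGI2 (-4.42), YMR206W (-4.29), SPG1 (-4.07), SPG4 (-3.85), YIG1 (-3.79) and YGR067C (-3.78) were the other largest falls. Of 39 general stress genes 35 fell and DDR48 alone rose (-1.37, 0.108), with the glycogen genes GSY1 (-3.14) and GLC3 (-2.72) among the lowest. Of 70 mitochondrial RP genes 47 fell and none rose (-0.63, 0.323), as did 19 of 49 respiration genes (-0.26, 0.138), for example KGD1 (-1.21). The 27 chaperone genes of Hsf1 went both ways, SSA2 (1.90) up and HSP42 (-1.77) down, with 4 higher and 10 lower. Of 17 hexose transport genes 2 rose, the regulator gene STD1 by 1.65 among them, and 5 fell, with HXT5 at -2.91. Of 71 amino acid biosynthesis genes 24 rose, for example SER2 (1.52) and ARO7 (1.27), and 4 fell.

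The cytosolic RP genes moved little in the control strain. Of 81, 27 rose and none fell at 60 min (median 0.23, adjusted p = 0.213 with an estimated correlation), and 16 rose at 30 min (0.18), with RPL22B (1.14) and RPS27A (0.86) the most raised at 60 min. The median was 0.14 at 60 min and 0.085 at 30 min without replicate a of YSS37 at time 0. It was 0.36 and 0.30 with values as deposited. At 30 min 816 genes were higher and 703 lower in YSS37, and 137 ribosome biogenesis genes had already risen (median 1.11). Adjusted over the list alone, 143 ribosome biogenesis, 30 non-fermentable carbon, 37 general stress, 61 mitochondrial RP and 26 cytosolic RP genes were called in these directions at 60 min. Centring each array on its median gave 942 higher and 1504 lower genes at 60 min, and 673 and 1049 at 30 min.

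The strains already differed before galactose. YSS89 had 1004 genes higher and 575 lower than YSS37, 242 and 124 of them by at least 2-fold. Each list median in brackets here is followed by its adjusted p with an estimated correlation. Ribosome biogenesis genes were higher in YSS89, 135 of 146 and none lower (1.14, 0.0291), and so were 19 of 28 genes for RNA polymerase I and III (0.67, 0.0431). The nucleolar protein gene NSR1 (2.01), the 60S assembly gene RPF2 (2.12), DBP2 (2.10), RPA12 (2.06) and RPA43 (1.42) were among them. AAH1 (2.15), YKL068W-A (2.37), YOR338W (3.35), the transcription factor gene TEA1 (2.07), ADY4 (2.22) and FDH1 (2.03) were also higher. Of 39 general stress genes 24 were lower and none higher (-0.84, 0.188, but a median of 0.035 with the round as a block), with the hexokinase gene HXK1 at -2.07 and the catalase gene CTT1 at -2.05. Of 27 Hsf1 chaperone genes 13 were lower and 2 higher (-0.51, 0.135), with BTN2 at -2.37 and SSA4 at -1.89. The sulfate permease gene SUL1 (-2.90), SPG1 (-2.62), HSP30 (-2.51), RGI1 (-2.42), YNL194C (-2.31), CIP1 (-2.24), ROQ1 (-2.19) and SDD1 (-2.06) were lower as well. Of 81 cytosolic RP genes 23 were lower, RPS7A (-0.78) and RPP2A (-0.71) among them, and 4 were higher, such as RPL7B (0.99), with a median of -0.14 (adjusted p = 0.231). Of 71 amino acid biosynthesis genes 10 were higher, CPA1 (1.60) and ARG3 (1.30) among them, and 17 lower, such as ARG1 (-1.14). RAP1, whose product binds RP promoters, was higher (0.48, adjusted p = 0.0231). MF(ALPHA)2 (-0.61) was lower among the 4 alpha-cell genes measured.

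The time 0 arrays of the strains came from different hybridization rounds, and the counts moved with the round. With the round as a block 31 genes were called, 25 higher and 6 lower, as the median standard error rose from 0.171 to 0.338. Ribosome biogenesis then had a median of 0.86 with 5 of 146 called, RNA polymerase I and III 0.70, Hsf1 chaperones -0.40 and general stress 0.035, with none called in these 3. Without replicates b and c of YSS89 at time 0 the count was 435 and general stress was at -0.28 with none called. With only the groups of the contrast in the fit 692 genes were called. Values as deposited gave 1732 higher and 405 lower genes and a cytosolic RP median of -0.27, and median centring gave 657 and 1342, a cytosolic RP median of -0.64 and an Hsf1 chaperone median of -0.91, and the median of all genes shifted by 0.17 and by -0.20. Adjusted over the list alone, 140 ribosome biogenesis genes were higher, and 26 general stress and 23 cytosolic RP genes were lower.

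Within 20 min of galactose the RP genes rose in YSS89. Of 5656 genes 430 were higher and 586 lower than at time 0, 87 and 105 of them by at least 2-fold. The ACT1 ratio of 3' to 5' probe sets, a sign of RNA quality, was 1.55 ± 0.031 on these 3 arrays, higher than on the other 21, and 1.27 ± 0.099 at time 0, and its part in the changes was not tested. Of 81 cytosolic RP genes 48 rose and none fell, with a median of 0.43 (adjusted p = 0.0118 with an estimated correlation). RPL22B rose by 2.06 and RPS26B by 1.56, and RPL17A (0.30) and RPL21B (0.29) were among the smallest called rises. HMO1, for a protein of RP and rRNA promoters, rose (0.58, adjusted p = 0.0316), while FHL1 was not called (0.20, adjusted p = 0.391). The HMO1 rise rested mainly on replicates b and c at time 0, with normalized log2 values of 8.26 and 7.95. Replicate a was at 8.71 at time 0, against 8.80, 9.03 and 8.82 on the arrays at 20 min. Of 146 ribosome biogenesis genes 21 rose, RIO1 (1.40) and UTP22 (1.14) among them, and none fell (adjusted p = 0.356 with an estimated correlation). FUR4 (3.21), the U3 RNA gene SNR17A (2.92) and the mitochondrial intron genes AI1 (2.80) and SCEI (2.55) rose as well, though inside the second hybridization round the last 3 were at 1.28, 1.86 and 0.97. Of 32 genes for non-fermentable carbon use 15 fell and none rose (median -0.75, adjusted p = 0.0393 with an estimated correlation), the glycerol kinase gene GUT1 (-1.32) among them. Of 49 respiration genes 24 fell and 1 rose, ACO1 (aconitase, -1.21) and IDH2 (-0.83) among the falls, with a median of -0.38 that turned to 0.026 with median centring. Of 70 mitochondrial RP genes 31 fell and none rose, for example MRPL40 (-1.03), with a median of -0.53 (adjusted p = 0.272 with an estimated correlation) that was -0.34 with the round as a block. The glycerol symporter gene STL1 (-2.53), the copper transporter gene CTR1 (-2.12), FMP48 (-2.70), CMR3 (-2.27), FDH1 (-2.17), SSH4 (-2.13), MSS2 (-2.08), YIG1 (-2.06), FRE7 (-2.04) and YGR035C (-1.98) were the largest falls. Adjusted over the list alone, 55 cytosolic RP genes rose, and 25 non-fermentable carbon, 32 respiration and 41 mitochondrial RP genes fell.

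The RP rise at 20 min stood in every treatment of the arrays that was run. A block for the round gave a cytosolic RP median of 0.45 and 274 called genes. Between arrays of the second round alone, 2 at 20 min and 1 at time 0, these were 0.47 and 172; without replicates b and c at time 0 323 genes were called, and with only the groups of the contrast in the fit 502. Where 1 array was left at time 0, its spread was taken from other groups. Without replicate c at time 0 the count was 654, and without replicate c at 20 min 656. Values as deposited gave an RP median of 0.75 with 291 genes higher and 889 lower, and median centring gave 0.93 with 600 and 420. Values as deposited shifted the median of all genes by -0.11.

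From 30 min on the RP genes stayed above time 0 in YSS89, and many respiratory and gluconeogenic genes were below it. At 30, 40 and 60 min 1269, 1350 and 1352 genes were higher and 1332, 1215 and 1120 lower than at time 0. Of 81 cytosolic RP genes 66, 68 and 63 rose and none fell, with medians of 0.76, 0.73 and 0.68. At 60 min RPS26B rose by 2.21 and RPL15A by 1.70, and RPL3 (0.50) and RPL5 (0.35) by less. FHL1 rose by 0.70 (adjusted p = 0.000961) and RAP1 by 0.49 (adjusted p = 0.0124). Ribosome biogenesis genes rose too, 119 of 146 at 60 min (median 0.70, adjusted p = 0.163 with an estimated correlation), UTP22 (1.63) and REX4 (1.43) among them, as did 18 of 28 genes for RNA polymerase I and III (0.54, 0.0987), such as RPC31 (1.07), and 24 of 39 translation factor genes (0.48, 0.222), such as GCD2 (1.0) and TIF3 (0.97). HMS2 (3.98), FUR4 (3.10), the RNA-binding protein gene SRO9 (2.84), the pentose phosphate gene GND1 (2.69) and SCEI (2.63, but 0.31 inside the second hybridization round) were among the largest rises. Of 32 genes for non-fermentable carbon use 30 fell and none rose (median -2.73), FBP1 by -7.34, MLS1 by -6.51, PCK1 by -6.16, ICL1 by -4.53 and the lactate permease gene JEN1 by -6.11. FDH1 (-6.21), the alcohol dehydrogenase gene ADH2 (-5.82), STL1 (-4.53), YGR067C (-4.32) and the pyruvate carrier gene MPC3 (-4.26) fell with them. Of 49 respiration genes 43 fell and none rose (-0.71), ACO1 by -2.19 and SDH4 by -1.97, and of 39 general stress genes 34 fell and none rose (-1.82), ALD4 by -3.31 and PRX1 by -3.23. Of 70 mitochondrial RP genes 54 fell and none rose (-0.76). Of 21 genes for glycolysis and fermentation 14 fell at 60 min and none rose, ENO1 by -2.06, with a median of -0.64 that was -0.081 with values as deposited and 0.026 with median centring. Amino acid biosynthesis genes split, 34 higher and 13 lower, with HIS6 (1.33) and LYS21 (1.07) up and MET2 (-2.75) and MET6 (-1.80) down. Of 7 a-cell genes 5 rose, BAR1 by 0.90, and ASG7 fell (-2.40), while the list was not called (adjusted p = 0.266, and 0.605 with an estimated correlation), and STD1 rose (1.84) while HXT5 fell (-3.44).

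With an estimated correlation the adjusted p for cytosolic RP genes was 0.0139, 0.0194 and 0.0244 at 30, 40 and 60 min. At 60 min it was 0.0101 for non-fermentable carbon use, 0.0113 for respiration, 0.0895 for general stress, 0.087 for glycolysis and 0.28 for mitochondrial RP genes. Adjusted over the list alone, 67 cytosolic RP and 127 ribosome biogenesis genes rose at 60 min, and 44 respiration, 30 non-fermentable carbon, 35 general stress and 57 mitochondrial RP genes fell. Fitted with the round as a block, 1618, 1694 and 1555 genes were called and the cytosolic RP medians were 0.83, 0.79 and 0.72. The mitochondrial RP median at 60 min was -0.43 with that block. Between arrays of the second round alone, 1 against 1 with the spread taken from other groups, the RP medians were 0.81, 0.82 and 0.73, and 1066, 1202 and 1157 genes were called. Values as deposited raised the RP medians to 1.37, 1.23 and 1.15 and median centring to 1.53, 1.34 and 1.26, and at 30 min values as deposited gave 834 genes higher and 1587 lower.

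**Figure D2:**
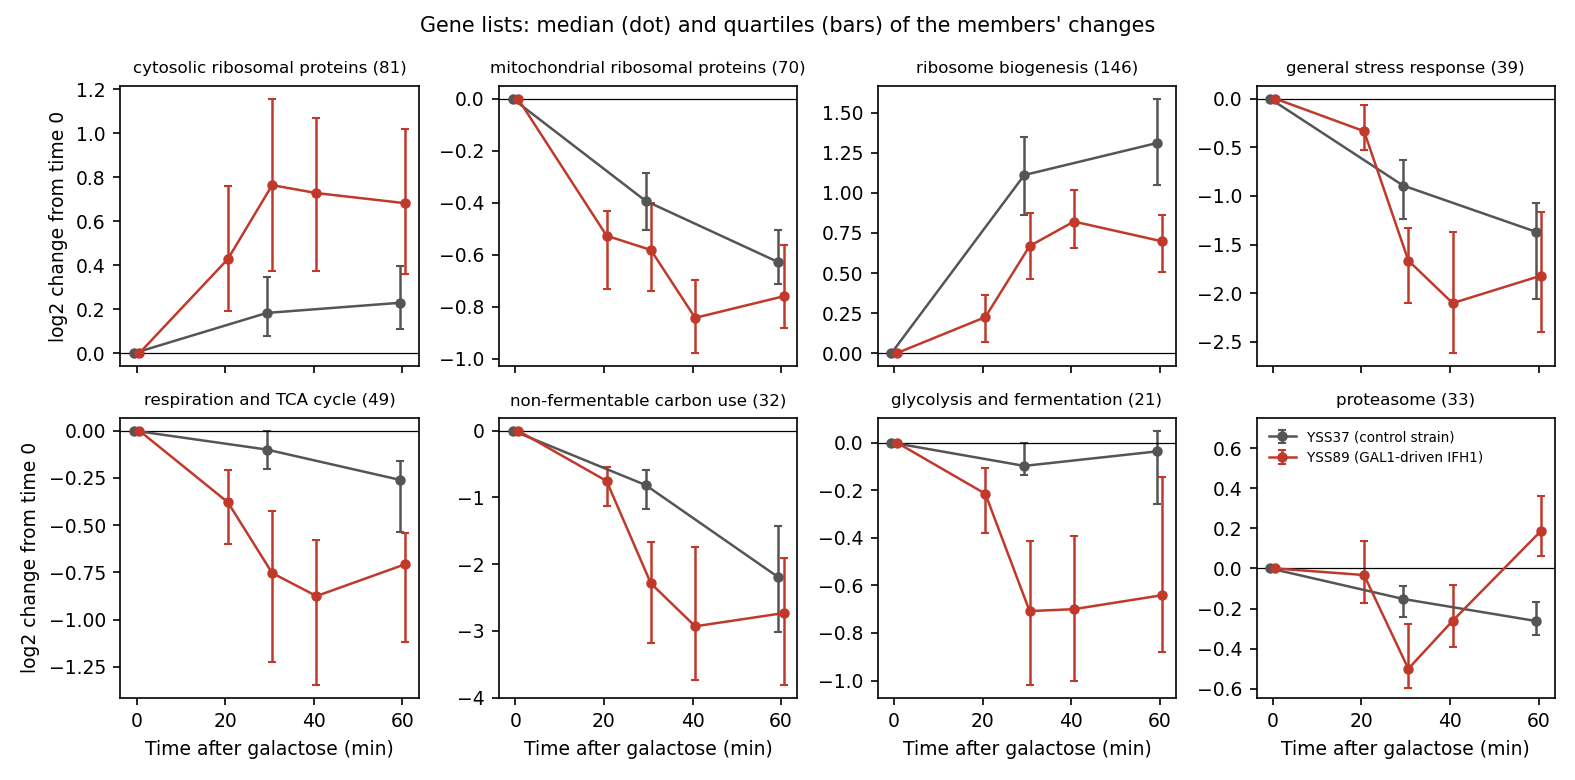
Median log2 change from time 0 of 8 gene lists in YSS37 and YSS89, with quartiles of the members and the number of genes measured in brackets. With each array centred on its median, the YSS89 medians turned above 0 for respiration at 20 min and for glycolysis at 20 and 60 min; for glycolysis at 20 min values as deposited did so too.

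Read array by array, the RP genes gave the same order of groups. These are the same genes and normalized values as in the fit, so this is not independent support. The mean of the 81 RP genes minus the array median was 4.79 ± 0.096 (SD, n = 3), 5.00 ± 0.046 and 5.05 ± 0.019 in YSS37 at 0, 30 and 60 min. In YSS89 it was 4.62 ± 0.047, 5.15 ± 0.046, 5.45 ± 0.003, 5.4 ± 0.005 and 5.34 ± 0.009 at 0, 20, 30, 40 and 60 min. YSS89 was below YSS37 before galactose (-0.17) and above it at 30 min (0.45) and at 60 min (0.29), with no overlap between the 3 and 3 arrays in each case (exact p = 0.1, the smallest that 3 against 3 arrays can give). Set against the mitochondrial RP genes in place of the array median, RP genes were above YSS37 by 0.86 at 30 min and 0.66 at 60 min, and before galactose the sign turned (0.12, exact p = 0.6). Against mitochondrial RP genes the YSS89 level was highest at 40 min (5.18), above 30 min (4.94) and 60 min (5.00). With values as deposited the differences between the strains, against the array median, were -0.58, 0.77 and 0.39 at 0, 30 and 60 min.

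**Figure D3:**
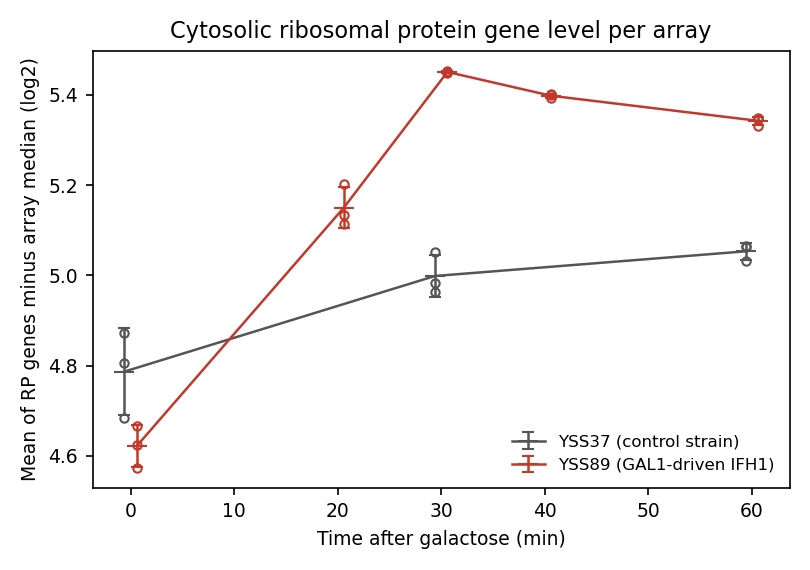
Mean log2 value of 81 cytosolic RP genes minus the array median, by strain and time after galactose. Circles are single arrays, and bars give the mean and SD of 3 arrays; set against mitochondrial RP genes, the difference between the strains at time 0 turned sign.

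The RP genes responded more to galactose in YSS89 than in YSS37. At 60 min the difference of the responses was called in 784 genes, 308 higher and 476 lower in YSS89. Of 81 RP genes 32 were higher and none lower, with a median of 0.39 (adjusted p = 0.0362 with an estimated correlation). RPS26B differed by 1.65 (adjusted p = 2.22e-05), RPL15A by 1.26 (adjusted p = 0.000686), RPL32 by 0.47 (adjusted p = 0.0437) and RPL14A by 0.45 (adjusted p = 0.0394). At 30 min 380 genes were higher and 622 lower, and 45 RP genes were higher and none lower, with a median of 0.52 (adjusted p = 0.0165 with an estimated correlation). When adjusted over the list alone, 50 RP genes were higher at 30 min, and 39 were higher and 1 lower at 60 min. Another 59 probe sets that name several RP genes each, left out of these counts, had 26 higher at 30 min and 18 higher at 60 min (median 0.39). FHL1 (0.52, adjusted p = 0.113) and HMO1 (-0.51, adjusted p = 0.188) were not called at 60 min, and of the 10 RP regulator genes IFH1 alone was called then, while at 30 min FHL1 (0.64, adjusted p = 0.0462) and RAP1 (0.66, adjusted p = 0.0383) were higher as well.

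**Figure D4:**
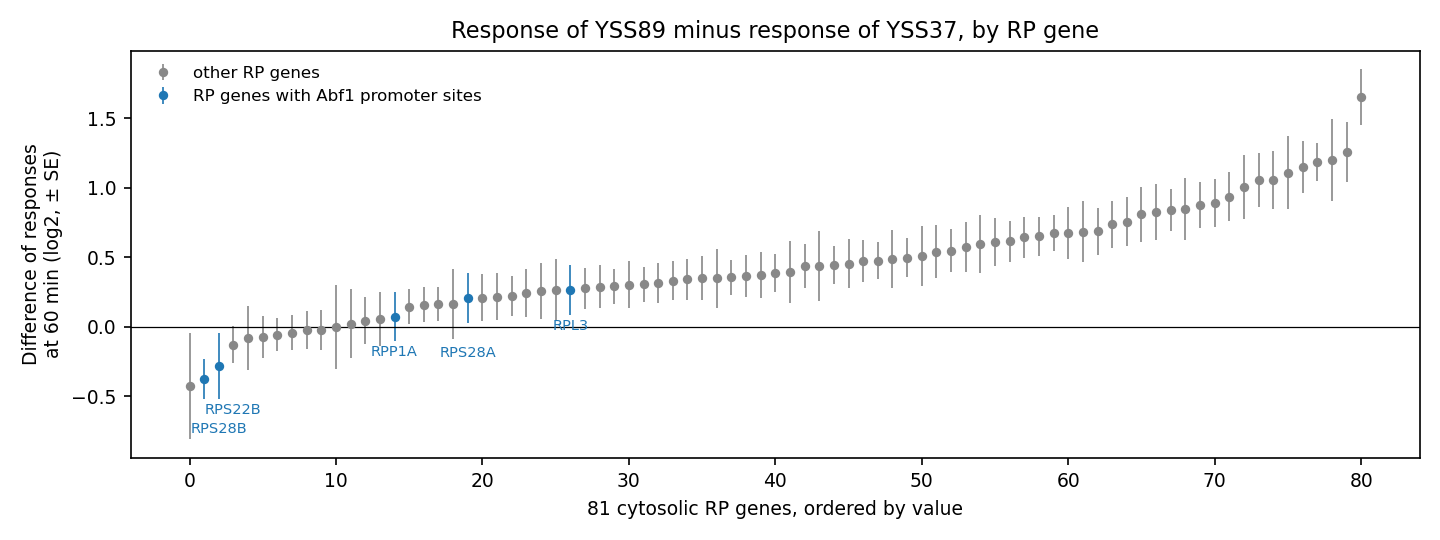
Response of YSS89 minus response of YSS37 at 60 min for 81 cytosolic RP genes, with standard errors. The RP genes with Abf1 promoter sites are named.

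Carbon metabolism and several other groups also responded differently, and in brackets each list median below is followed by its adjusted p with an estimated correlation. Of 49 respiration genes 17 were lower at 60 min (-0.46, 0.0273), ACO1 by -1.53 and IDH2 by -1.32, and 32 at 30 min (-0.69, 0.0139). Median centring brought these medians to -0.043 and -0.26. Of 32 genes for non-fermentable carbon use 12 were lower and 1, CIT2 (1.34), higher at 60 min (-0.69, 0.0987), and 23 lower and 1 higher at 30 min (-1.38, 0.0251). MLS1 (-2.80), PCK1 (-2.49), JEN1 (-2.46) and ADH2 (-3.98) had the larger falls in YSS89. Of 21 glycolysis and fermentation genes 10 were lower at 60 min, such as ENO1 (-1.58), and 11 at 30 min, but the medians (-0.38, 0.0937 and -0.58, 0.0365) turned to 0.094 and 0.048 with median centring. Of 41 cell cycle genes 16 were lower at 60 min and none higher (-0.44, 0.0277), among them PCL1 (-1.97) and CDC6 (-1.89), with a median of -0.27 with median centring. Of 33 proteasome genes 14 were higher and none lower at 60 min (0.44, 0.0288), RPN1 by 0.86 and RPN9 by 0.84, and their median was 0.70 with median centring, while at 30 min 6 were lower and none higher (-0.35, 0.188). Of 4 histone genes measured 2 were lower, HTB2 (-1.17) and HHO1 (-0.86). Among the lowest values were the transporter genes PHO84 (-3.12) and GIT1 (-2.94), the phosphatase gene PHM8 (-2.39), ECM13 (-2.99), the methionine gene MET2 (-2.68) and the proteinase A inhibitor gene PAI3 (-2.41). The highest values after IFH1 were those of YJR115W (2.99), PRR2 (2.77), BTN2 (2.61), the U6 RNA gene SNR6 (2.47), SPG1 (2.46), SCEI (2.33), YMR230W-A (2.19), the RNase P RNA gene RPR1 (2.08) and SNR17A (2.08). BTN2 was already lower in YSS89 before galactose, and that lower start is part of its value. Within hybridization rounds YJR115W was at 1.14, SNR6 at 1.83, RPR1 at 1.60, SNR17A at 0.43 and SCEI at -0.17, none of them called, and SPG1 was at -0.16 in the direct comparison of the strains at 60 min.

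Ribosome biogenesis genes responded less in YSS89, 54 of 146 lower and 1, UTP22 (1.10), higher at 60 min (median -0.68, adjusted p = 0.154 with an estimated correlation). Compared directly at 60 min they were higher in YSS89, with a median of 0.49. NSR1 (-1.94) and DBP2 (-1.80) turned to 0.068 and 0.30 in the same way. With the round as a block 208 genes were called at 60 min and 426 at 30 min, and the RP medians were 0.45 and 0.61. Within hybridization rounds 1 YSS89 array was left for each time, and the spread was taken from other groups. There 782 of the 784 genes called at 60 min had the same sign, and the RP medians were 0.49 and 0.56. The count at 60 min was 512 without replicate b of YSS37 at time 0, 282 without replicates b and c of YSS89 at time 0, 1230 with array weights and 325 with only the groups of the contrast in the fit. The count at 30 min was 512 without those 2 YSS89 arrays and 516 with only the groups of the contrast. Values as deposited gave RP medians of 0.78 at 60 min and 1.05 at 30 min with 208 genes higher and 644 lower at 60 min and 222 and 884 at 30 min, and the median of all genes shifted by -0.15 and by -0.16. Median centring gave RP medians of 1.07 and 1.34 with 679 higher and 307 lower and 598 and 388, and that median shifted by 0.13 and by 0.14. Adjusted over the list alone, 26 respiration, 13 non-fermentable carbon, 19 cell cycle and 79 ribosome biogenesis genes were lower at 60 min and 15 proteasome genes higher.

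Compared directly after galactose, YSS89 had many RP and ribosome biogenesis genes higher and many stress and glycolysis genes lower than YSS37. With an estimated correlation the adjusted p at 30 and 60 min was 0.0848 and 0.134 for RP genes, 0.154 and 0.23 for ribosome biogenesis and 0.0937 and 0.0848 for general stress. At 30 min 1323 genes were higher and 1132 lower, and at 60 min 934 and 643. Of 81 RP genes 49 were higher at 30 min (median 0.38) and 32 at 60 min (0.27), none was lower at either time, and 113 and 68 of 146 ribosome biogenesis genes were higher (0.72 and 0.49). Of 39 general stress genes 35 and 29 were lower (-1.43 and -0.98), and glycolysis genes were lower at 60 min, 13 of 21 (-0.68, adjusted p = 0.0113 with an estimated correlation). Hsf1 chaperone genes were lower at 30 min, 24 of 27 (-0.96, 0.0362), and 7 were lower and 1 higher at 60 min (-0.13, 0.445). Proteasome genes were lower at 30 min, 26 of 33 (-0.52, 0.037), and higher at 60 min, 12 of 33 (0.28, 0.138). There were 55 and 32 higher RP genes when adjusted over the list alone. A block for the round left 593 and 455 called genes, with RP medians of 0.37 and 0.26, and between the 2 arrays at 60 min that share a round, with the spread taken from other groups, the RP median was 0.24 and 204 were called. Those 2 arrays were from different chip lots. Values as deposited gave RP medians of 0.82 and 0.50, and median centring 0.74 and 0.42.

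RP genes with Abf1 sites in their promoters had a lower difference of responses than the other RP genes. The 5 measured, RPL3, RPP1A, RPS22B, RPS28A and RPS28B, had a mean difference of responses of -0.02 at 60 min against 0.48 for the other 76 (difference -0.50, permutation p = 0.00614), and of 0.14 against 0.61 at 30 min (-0.47, permutation p = 0.0203). RPS22B (-0.37, adjusted p = 0.0881) and RPS28B (-0.28, adjusted p = 0.469) were not called at 60 min, but RPS28B was higher with median centring (0.73, adjusted p = 0.0478). At 30 min the difference was -0.27 (permutation p = 0.0812) with values as deposited, -0.27 (permutation p = 0.0815) with median centring and -0.37 (permutation p = 0.0644) with the mean of the probe sets of a gene. In the direct comparison of the strains it was absent at both times, 0.019 (permutation p = 0.908) at 30 min and -0.01 (permutation p = 0.92) at 60 min. The lower difference of responses of these genes is thus a strain difference already present before galactose, between arrays of different hybridization rounds.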

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

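The look at balanced splits and the values within hybridization rounds were chosen after the result was seen, and the other tests in this part were planned. The strains differed in their response to galactose by a test of the difference itself, and the genes and lists below are named for that reason. At 30 min the median difference of responses was 0.52 for cytosolic RP genes, -0.69 for respiration and the TCA cycle, -1.38 for non-fermentable carbon use and -0.58 for glycolysis and fermentation, where the last turned to 0.048 with each array centred on its median and respiration was at -0.26. At 60 min it was 0.39 for cytosolic RP genes, -0.46 for respiration and the TCA cycle (-0.043 with that centring), -0.44 for cell cycle genes and 0.44 for proteasome genes. The proteasome median at 30 min was -0.35, and the list was not called then with an estimated correlation.

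Among single genes the largest differences of responses at 60 min were above 0 for IFH1 (3.89), YJR115W (2.99), PRR2 (2.77), BTN2 (2.61), SNR6 (2.47), SPG1 (2.46), SCEI (2.33), YMR230W-A (2.19), RPR1 (2.08) and SNR17A (2.08), and below 0 for ADH2 (-3.98), PHO84 (-3.12), ECM13 (-2.99), GIT1 (-2.94), MLS1 (-2.80), MET2 (-2.68), PCK1 (-2.49), JEN1 (-2.46), PAI3 (-2.41) and PHM8 (-2.39). Within hybridization rounds SNR17A was at 0.43 and SCEI at -0.17, and SPG1 was at -0.16 in the direct comparison of the strains. The value of BTN2 includes its lower start in YSS89 before galactose. Outside the genes tested by name, 85 of 2771 probe sets that name no gene or several were called in the same contrast, 46 higher and 39 lower in YSS89.

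Other splits of the same arrays were counted for each result. For the difference of responses at 30 min 4 of 100 drawn splits of the 12 arrays, the real one included, gave as many called genes (1002, highest other 2100). At 60 min 2 of 100 did (784, highest other 864), and each share is under 0.05. The splits carry real strain and time effects, which can raise or lower their counts, so the share cannot decide whether chance gave these counts. For the RP median 11 of 100 splits at 30 min (0.52, highest other 0.99) and 19 of 100 at 60 min (0.39, highest other 0.70) were as large, so this count does not exclude chance for it. All other splits that were as large held unequal numbers of arrays of a strain or a time in the 2 groups, which points to the structure of the samples. Among the 18 and 15 drawn splits balanced for both, at most 0 and 1 genes were called and the highest RP medians were 0.29 and 0.24. The groups of these splits mix arrays of different strains and times, which widens their spread, so the low counts do not exclude chance either.

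With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In each of these contrasts 1 of the 10 splits, the real one, gave as many genes: 1579 before galactose (highest other 62), 2455 for the strains at 30 min (0) and 1577 at 60 min (1), 1519 for YSS37 at 30 min (6) and 2354 at 60 min (5), and 1016, 2601, 2565 and 2472 for YSS89 at 20, 30, 40 and 60 min (4, 2, 0 and 0).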

How the results depend on the processing

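The fits without replicates b and c of YSS89 at time 0, within hybridization rounds, and with probe sets of several RP genes were chosen after the data were seen; the other alternatives were planned. Counts of called genes in the contrasts that hold YSS89 moved most with the hybridization round, as the strains share few rounds and a block leaves fewer arrays to compare. Under a block for the round they were 31 before galactose, 593 and 455 for the strains at 30 and 60 min, 274, 1618, 1694 and 1555 for YSS89 at 20, 30, 40 and 60 min, and 426 and 208 for the differences of responses. For YSS37 at 30 and 60 min the block gave 1578 and 2165 against 1519 and 2354. Within hybridization rounds they were 204 for the strains at 60 min, 172, 1066, 1202 and 1157 for YSS89, and 200 and 97 for the differences of responses. Without the 2 arrays of YSS89 at time 0 they were 435 before galactose, 323 at 20 min, and 512 and 282 for the differences. A random block for the round was not run.

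With only the groups of the contrast in the fit the counts were 692 before galactose, 820 and 1615 for YSS37 at 30 and 60 min, 502 for YSS89 at 20 min, and 516 and 325 for the differences of responses, as fewer arrays give the spread. Array weights gave 1230 for the difference at 60 min, and the cause was not tested. Direct strain differences in place of differences of responses called 2455 and 1577 genes. The difference before galactose enters there and the median standard error is 0.171 against 0.242, and these were not separated. Leaving out 1 array moved the difference at 60 min to between 512 and 989, and YSS89 at 20 min to between 654 and 1061. The RP median then stayed between 0.35 and 0.46, and between 0.41 and 0.46. Replicate letters were not taken to pair the arrays, as 32 of 84 pairs of arrays with the same letter had residuals correlated over 0.1 (mean r 0.054, -0.415 to 0.551) and not all. Of other pairs 34 of 168 did (mean r -0.027), and 17 of 24 arrays correlated best with their own letter, a hint from the data and not the design. A block by letter gave 818 genes for the difference at 60 min and 1018 at 30 min, with RP medians of 0.39 and 0.52, while 858 and 1066 genes were called with a block by strain and letter.

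RP medians lost their list call with the estimated correlation before galactose (adjusted p = 0.231), for the strains at 30 and 60 min (0.0848 and 0.134) and for YSS37 at 30 and 60 min (0.204 and 0.213), with medians of -0.14, 0.38, 0.27, 0.18 and 0.23. The RP level per array moved when set against mitochondrial RP genes, which themselves fell: 0.12 before galactose, a turn of sign, 0.86 and 0.66 for the strains at 30 and 60 min, 0.63 and 0.89 for YSS37, and 1.07, 1.37, 1.61 and 1.44 for YSS89 at 20, 30, 40 and 60 min. With values as deposited it was -0.58 before galactose, 0.77 and 0.39 for the strains, and 0.94, 1.60, 1.35 and 1.24 for YSS89. With the mean of the probe sets it was 0.88 and 0.83 for YSS89 at 30 and 40 min. Without the 2 arrays it was -0.21 before galactose and 0.58, 0.88, 0.83 and 0.77 for YSS89. The Abf1 difference at 30 min was -0.27 with values as deposited and with median centring, and -0.37 with the mean of the probe sets. For the direct difference it was 0.019 at 30 min and -0.01 at 60 min, so it lies in the difference before galactose.

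Among the genes and lists whose values are given in the report, directions turned in these cases. Some list members whose direction turned are not named and are not counted here. With median centring respiration in YSS89 at 20 min was at 0.026, glycolysis at 0.23 at 20 min (0.053 with values as deposited), 0.026 at 60 min, and 0.048 and 0.094 in the differences of responses, and RPS28B was at 0.73 in the difference at 60 min. With the round as a block general stress before galactose was at 0.035, and within rounds SCEI was at -0.17 in the difference at 60 min. For these the cause was not tested. In the direct difference at 60 min, from which the difference before galactose is not taken off, ribosome biogenesis was at 0.49, NSR1 at 0.068, DBP2 at 0.30, RPS28B at 0.63 and SPG1 at -0.16, and the turn is the difference before galactose.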

Other observations

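The tests of the separate time 0 arrays for mitochondrial transcripts and small RNAs, and of galactose before time 0, were chosen after the results were seen, as were the fits within hybridization rounds and without 2 arrays. Proteasome genes were called in different directions at different times in YSS89. Of 33, 22 were lower at 30 min and none higher (median -0.50, adjusted p = 0.0753 with an estimated correlation), and at 60 min 10 were higher and none lower (0.19, adjusted p = 0.327, and a median of 0.10 with values as deposited), RPN9 (0.67) and PRE6 (0.59) among them. Of these 10, 3 were among the 22. In YSS37 13 were lower and none higher at 60 min (-0.26, adjusted p = 0.188). BTN2, a chaperone gene lower in YSS89 before galactose (-2.37), had risen there by 60 min (1.47).

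Some small structured RNAs and mitochondrial transcripts rose in YSS89. Of 64 genes in a small RNA set and 19 mitochondrial transcripts measured, 34 were higher at 60 min than at time 0 and 0 lower. These were 26 of the small RNA set (median of these 1.13) and 8 mitochondrial transcripts (1.37). The set holds mostly small nuclear and nucleolar RNAs, but also the RNase P RNA gene RPR1 and RPR2, which encodes a protein of RNase P. Both are among the 26. In YSS37 at 60 min 6 of the 64 and 19 genes were higher, and the difference of responses was called in 12.

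The mitochondrial and small RNA rises were weighed against the 2 time 0 arrays that were hybridized apart, on which rRNA signals were low. Inside the second hybridization round the 8 mitochondrial transcripts changed by a median of 0.055 (SE 0.335), and the time 0 array of that round lay above the other 2 by 1.43, so RNA or labelling of those 2 arrays may explain this part. Over all 19 the change was 0.035 (SE 0.272) inside that round and 0.66 in all arrays. The 26 genes of the small RNA set, the protein gene RPR2 among them, still rose by a median of 0.82 (SE 0.18) there. But this sets 1 array against 1 for genes chosen on these arrays. Over all 64 the change was 0.35 (SE 0.172) against 0.43 in all arrays, so the 2 separate time 0 arrays cannot be told apart from other causes for this part. A difference between the first 2 rounds could not enter either rise, as no YSS89 array was in the first round. That answer was fixed by the design and is not the result of a test. The 1 array of YSS37 at 60 min in the second round lay at -0.17 (SE 0.29) from the other 2 for the mitochondrial part. For the small RNA part it lay at 0.15 (SE 0.156). A difference of the third round, which held later YSS89 arrays, was not tested by itself. The strain and the galactose treatment stay open as explanations and were not tested apart.

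The larger RP response in YSS89 was weighed against 3 technical explanations. With the quantile step left out or replaced by median centring the median difference of responses at 60 min was 0.78 at the lowest, with each response inside 1 round it was 0.49 (0.45 with the round as a block), and on 51 probe sets marked as specific to 1 gene it was 0.35, against 0.44 on 30 shared ones. The values within rounds and on specific probe sets stayed near the 0.39 found in all arrays or above it. Without the quantile step the median was larger, at 0.78 or more, so its size depends on the normalization. Part of the 0.39 is the lower start of YSS89, whose RP level per array differed from YSS37 by -0.17 before galactose and by 0.29 at 60 min. Set against mitochondrial RP genes, the difference before galactose was 0.12. The induced IFH1 may be the reason for the rest, as a hypothesis from the same data for which no test was made. The source of the strain difference before galactose stays open.

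Ribosome biogenesis genes stood higher in YSS89 before galactose. With the round as a block their median was 0.86, and without the 2 separate time 0 arrays it was 0.91, against 1.14 in all arrays. With that block 5 of 146 were called, since the median standard error over all genes rose from 0.171 to 0.338, and their mean difference went from 1.11 (SE 0.109) to 0.89 (SE 0.22). Both fits rest on replicate a of YSS89 at time 0, since the fourth round held replicates b and c alone. They cannot separate the round from the strain, as no time 0 arrays of the strains share a round. Nor can they separate the chip lot from the strain, as that replicate was not from the lot of the YSS37 arrays. Galactose in the cultures before time 0 is argued against by GAL1, GAL2, GAL7 and GAL10, whose median difference was -0.11, and by IFH1 under the GAL1 sequence (0.009), although GAL3 was higher (0.47). A difference in growth state or in strain background could be the source and was not tested.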
